A study of Mus musculus with 6 samples.

How the data were processed

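RNA was sequenced from dendritic cells sorted out of ID8 tumours of C57BL/6 mice at day 23, from wild-type mice (WT, 3 libraries) and from mice in which XBP1 was deleted in CD11c-positive cells (XBP1-KO, 3 libraries). Per the labels' protocols, total RNA was isolated separately for each of the 3 samples per genotype and libraries were made by standard Illumina protocols. The labels do not say that the samples came from separate animals, so p-values measure the spread between these samples. The sort gate, the strand setting, the aligner and the gene annotation are not given in the sources used here.

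The deposited count table holds whole-number counts for 23225 gene symbols in 6 libraries, not normalized. Per the submitters' processing notes, RSEM, edgeR and the mouse build mm9 were used, with no version and no role stated. RSEM gives estimates that need not be whole, and no source says how the whole numbers were reached. A second deposited table holds CPM values for 13946 genes. Each of its values equalled the CPM of the deposited count over the library's total, with a largest difference of 5.1e-11, and its genes were exactly those with a CPM above 1 in at least 2 of the 6 libraries. The columns of both tables name the genotype and carry no replicate number. The libraries of a genotype are therefore called a, b and c in the order of the columns, and the letter is only a name that pairs nothing. No column was left out.

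Counts as deposited were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default settings, which left 15958 genes. Libraries were scaled by TMM factors, a negative binomial model with genotype as its only term was fitted by glmQLFit with robust estimation, and genotype was tested two-sided by the quasi-likelihood F test. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a gene was called changed under 0.05. Standard errors are the fold change divided by the square root of F. CPM values in the text are TMM-normalised, with the SD over the 3 libraries of a genotype. A gene is said to have risen or fallen only when it was called.

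Gene lists were written before the data were examined, as was the main test, the alternatives and the rule for named genes. They held 38 lists with 723 memberships, of which 699 matched a row of the table, by symbol or by an unambiguous older or newer symbol in the RefSeq table of the mouse assembly GRCm38, and 668 were tested. That table was used only for names, gene order, transcript length and GC content, since its build is not that of the counts. Each list was tested two-sided against all other tested genes with camera in limma 3.58.1 on log2 CPM with a preset inter-gene correlation of 0.01, adjusted over the 38 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction, were alternatives. With an estimated correlation camera also refers its statistic to the few residual degrees of freedom of 6 libraries. A list can therefore fail it without a high correlation between its genes. A count adjusted over the list alone uses only that list's p-values. The triglyceride list is the set of genes that the study itself named from these samples.

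The rule for named genes took Xbp1, the 8 genes with the largest fold change in each direction among called genes with a mean CPM of at least 5 and no overlap between the genotypes, and, of each list of pathways, up to 3 called members with the smallest p or otherwise the member with the smallest p. Of each list of cell type markers or RNA quality it took the 2 members with the highest mean CPM and up to 2 called members. All members of the triglyceride list were named. Genes named outside this rule are said to be so.

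The test was checked on simulated counts drawn from the means and depths of these libraries, 3 against 3, with 200 changed genes among 15523 tested. At a 2-fold change 72% of the 100 changed genes were recovered and at a 4-fold change 100%, with 9 false calls. A list shifted by -0.35 was found by camera and an unshifted list was not. Genes were simulated independently, so this check says nothing of camera where the genes of a list move together. Changed genes and list genes were taken only above a minimum level, so recovery is not known for genes below it.

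Libraries held between 26946349 and 32709100 counts. At this depth the spread between libraries, with a common biological coefficient of variation of 0.25, limits the precision for most genes, and counting error matters only for genes of a few counts. No pair of libraries of a genotype agreed within sampling noise, with chi-square values per degree of freedom between 22.5 and 74.5 over genes of at least 20 counts.

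The alternatives were DESeq2 1.42.0, limma-voom, the likelihood ratio test of edgeR, other scalings, other filters on low counts, estimation without robustness, the deposited CPM values tested with limma on log2(value + 1) and log2(value + 0.1), other thresholds, and each library left out in turn. After the data were seen, the authors' gene filter, the removal of each library's trend over GC content and transcript length by splines of 5 degrees of freedom, a score of T and NK cell genes as a covariate, libraries WT b and XBP1-KO b as a batch term, the other 4 libraries alone, and a list without Itgb2 were added. Bounds of a list's median come from 10000 bootstrap draws of its genes. Such genes are not independent replicates, so the bounds leave out the spread between libraries. Figures were drawn with matplotlib 3.10.9. Reads of near-identical genes, such as the Ly49 (Klra) family and the T cell receptor segments, can be split by the counting, and their values are uncertain to that extent.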

Results

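The data were RNA-seq counts of dendritic cells sorted from tumours of ID8, a mouse ovarian cancer line that grows in the peritoneal cavity with ascites. There were 3 WT libraries and 3 XBP1-KO libraries, all of day 23. XBP1 is a transcription factor that the ER stress sensor IRE1 activates by splicing its mRNA, and it drives genes of the secretory pathway. The WT libraries a, b and c held 29626295, 26946349 and 32709100 counts and the XBP1-KO libraries a, b and c 27706508, 28342151 and 31325627. Cd74, the invariant chain of MHC class II, took between 5.93% and 9.14% of the counts of a library. On the first principal component of log2 CPM, with 33.5% of the variance, the WT libraries lay at -32.8, 9.6 and -59.5 and the XBP1-KO libraries at 29.4, 37.5 and 15.8. On the second, with 22.2%, libraries WT b and XBP1-KO b stood apart at 38.3 and 30.1, while the other 4 lay between -45 and -1.

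The targeted gene was examined first. Xbp1 had a normalised level of 64.2 ± 14.3 CPM in WT (SD, n = 3) and 34.6 ± 5.07 CPM in XBP1-KO (SD, n = 3). Its counts were 1903, 1376 and 2300 in the WT libraries and 889, 916 and 1331 in the XBP1-KO libraries, so that every XBP1-KO value lay below every WT value. The log2 fold change was -0.89 (SE 0.18), with an adjusted p of 0.0545 in edgeR's quasi-likelihood test, which did not pass the threshold. It passed without library WT b, with an adjusted p of 0.0466, and not without any other library, where the adjusted p reached up to 0.301. It also passed with DESeq2 (0.00148), the likelihood ratio test (0.00512), no filter on low counts (0.00731), a filter at a CPM of 1 (0.0459), the authors' gene filter (0.0464), libraries WT b and XBP1-KO b as a batch term (0.0112) and the other 4 libraries alone (0.0496). With the T and NK score as a covariate its log2 fold change was -0.23, with an adjusted p of 0.882. The counts are per gene and do not separate transcripts with and without the deleted part of the gene.

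The comparison of the genotypes asks how loss of XBP1 in CD11c-positive cells changes the transcriptome of dendritic cells in the tumour. Of 15958 genes tested, 71 changed, with 25 higher and 46 lower in XBP1-KO, and 36 of them changed at least 2-fold (23 higher and 13 lower). At an unadjusted p under 0.05 there were 2051 genes where chance gives 798, and the values of 19.2% of the tested genes did not overlap between the genotypes where chance gives 10%. The 8 largest rises under the rule were genes known from natural killer and T cells. Xcl1, a chemokine of activated lymphocytes, rose from 5.39 ± 1.13 to 21.4 ± 3.14 CPM, and the Ly49 receptor genes Ly49A, Klra7 and Klra21 rose by 1.94, 1.83 and 1.73 on the log2 scale. Nkg7, a protein of cytotoxic granules, rose from 20.4 ± 4.92 to 69.4 ± 20.6 CPM, and Ms4a4b from 28.1 ± 5.57 to 83.5 ± 13.4 CPM. Cd3e of the T cell receptor complex rose from 5.4 ± 1.61 to 16.2 ± 3.56 CPM, and Ncr1, the NK cell receptor NKp46, from 6.68 ± 1.56 to 19.3 ± 7.38 CPM. The 8 largest falls were Il12b, Itgb2, Ptgir, Hyou1, Rps6kc1, Slc5a3, Plekhn1 and Nucb2. Il12b, the p40 subunit of IL-12 and IL-23, fell from 26.5 ± 7.85 to 8.26 ± 2.78 CPM. Itgb2, the beta chain CD18 of the leukocyte integrins, fell from 1884 ± 92.3 to 715 ± 166 CPM. Ptgir, the prostacyclin receptor, fell from 60.9 ± 21.6 to 23.4 ± 3.29 CPM. Nucb2, a calcium-binding protein, fell from 88.9 ± 21.6 to 40.4 ± 2.26 CPM, and Slc5a3, an inositol transporter, from 28.9 ± 6.31 to 13.1 ± 2.09 CPM. Plekhn1 fell from 11.1 ± 0.419 to 5.03 ± 0.716 CPM and Rps6kc1 from 24.3 ± 0.91 to 10.6 ± 3.06 CPM. Adjusted p-values of these 16 genes in edgeR's quasi-likelihood test lay between 0.00279 and 0.0489. The number of changed genes was 38 without WT a, 40 without WT b, 5 without WT c, 13 without XBP1-KO a, 154 without XBP1-KO b and 16 without XBP1-KO c, and of the 8 falls named here 1 passed without WT c, XBP1-KO a or XBP1-KO c and of the 8 rises 3 passed without WT c. With upper quartile scaling 23 genes were higher and 27 lower, and with library size alone 13 were higher and 12 lower. With libraries WT b and XBP1-KO b as a batch term 426 changed, and in the other 4 libraries alone 70, of which 36 were among the 71.

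Genes of the secretory pathway lay lower in XBP1-KO as lists, in a test with a preset correlation, and no list passed with an estimated correlation (adjusted p = 0.26 to 0.52). Over 5 lists with 142 tested genes, 110 lay lower, 11 fell and none rose, 44 fell when adjusted over these 142 genes together, and the median log2 fold change was -0.22. With library size alone, which moved the median of all genes from 0.057 to 0.136, the median went from -0.164 to -0.084 for chaperones, -0.171 to -0.089 for N-glycosylation and -0.121 to -0.035 for degradation. Among 29 ER chaperones and foldases, 22 lay lower and 2 fell. Hyou1, a chaperone of the ER lumen, fell from 62.8 ± 7.66 to 25.4 ± 6.58 CPM, and Pdia4, a disulfide isomerase, from 534 ± 83.7 to 317 ± 37.1 CPM. Hspa5, the ER chaperone BiP, which was named after its values were seen, had 1288 ± 140 CPM in WT and 1152 ± 159 CPM in XBP1-KO, with an adjusted p of 0.672. Of 23 genes of ER translocation and signal peptide processing, 19 lay lower and 2 fell. Sec61a1, the channel of the translocon, fell from 419 ± 64.6 to 206 ± 27.8 CPM, and Spcs3, a subunit of signal peptidase, from 494 ± 44.8 to 295 ± 22.4 CPM. Of 32 genes of N-glycosylation, 23 lay lower and 5 fell. Among these were Stt3a, a catalytic subunit of oligosaccharyltransferase, from 353 ± 36.2 to 180 ± 19.3 CPM, Ugcgl1, the glucosyltransferase of glycoprotein folding control, from 124 ± 18.9 to 68.2 ± 5.03 CPM, and Mlec, the ER lectin malectin, from 77.4 ± 6.11 to 44.1 ± 5.35 CPM. Of 36 genes of ER-to-Golgi traffic, 30 lay lower and 2 fell. Surf4, a cargo receptor, fell from 167 ± 20.6 to 89.3 ± 12.2 CPM, and Sec24d, a coat protein of COPII vesicles, from 43.1 ± 5.38 to 21.2 ± 5.92 CPM. Of 22 genes of ER-associated degradation, 16 lay lower and none passed. The smallest p was that of Os9, with 60.9 ± 2.82 CPM in WT and 41.4 ± 2.86 CPM in XBP1-KO with an adjusted p of 0.0877.

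With camera's preset correlation the adjusted p was 0.00013 for chaperones, 0.00011 for translocation, 0.00023 for N-glycosylation, 1.7e-09 for ER-to-Golgi traffic and 0.021 for degradation, all of them lower in XBP1-KO. With an estimated correlation none of the 5 passed, with adjusted p = 0.26, 0.37, 0.37, 0.26 and 0.52 in that order. The estimated correlations were 0.013, 0.179, 0.121, 0.08 and 0.12 in that order. That of chaperones lay near the preset 0.01, yet camera's unadjusted p went from 1.5e-05 to 0.013. For that list the loss of the call came mostly from the fewer degrees of freedom and not from correlation. Adjusted over the list alone, 7, 7, 9, 18 and 2 of their genes fell in that order. The mean log2 CPM of the degradation list overlapped between the genotypes, with 1 XBP1-KO library below every WT library. The call of the degradation list ended without WT c, with an adjusted p of 0.11, without XBP1-KO b, with 0.28, and in the 4 libraries other than WT b and XBP1-KO b, with 0.15. Of the 11 called secretory genes, 6 passed without WT a, 4 without WT b, 10 without XBP1-KO b and 0 without WT c, XBP1-KO a or XBP1-KO c, while all 11 lay lower in each of these fits. Across all genes, which are not independent replicates, the fold change had a Spearman correlation of -0.198 with transcript length and 0.028 with GC content. T and NK cell genes were higher in the same XBP1-KO libraries, with a mean log2 CPM of 3.83 ± 0.37 against 2.88 ± 0.13 in WT (SD, n = 3). All 30 cytosolic ribosomal protein genes lay higher, with a list adjusted p of 0.00026, and an adjusted p = 0.72 with an estimated correlation.

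**Figure D1:**
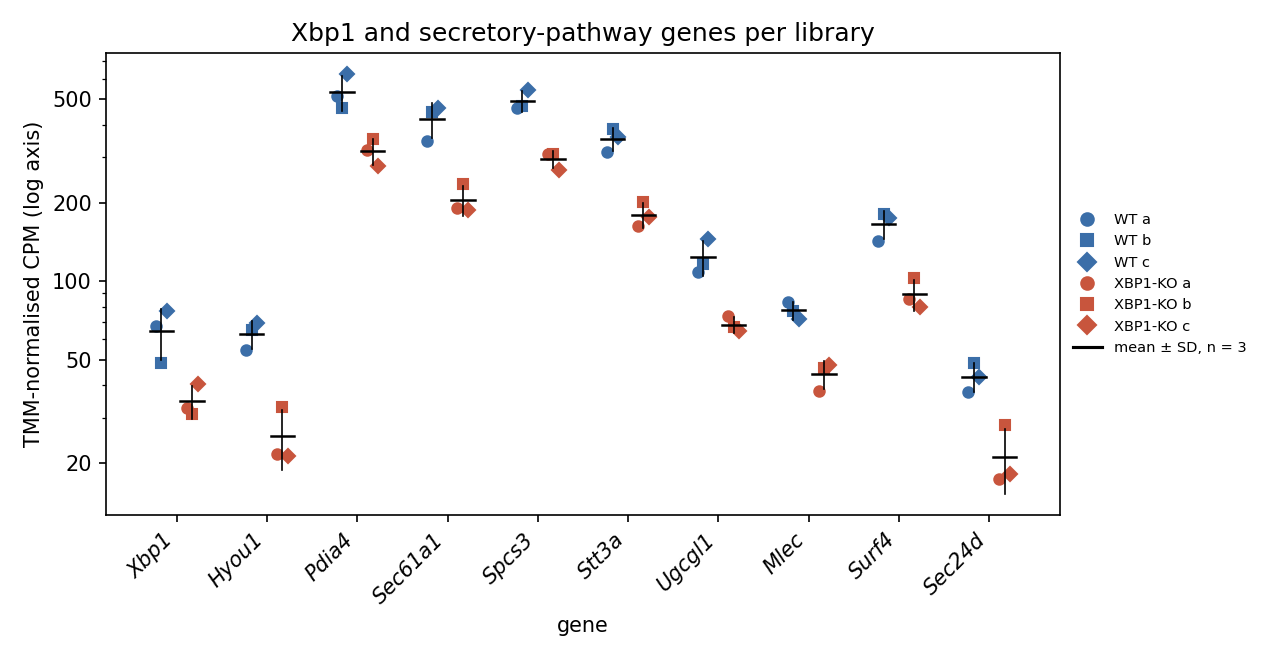
Normalised level (TMM-normalised CPM, log axis) of Xbp1 and of 9 called genes of the secretory pathway in each library, with the mean and SD of the 3 libraries of each genotype. For each gene every XBP1-KO library lies below every WT library; Sec61a1 had means of 419 and 206 CPM.

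**Figure D2:**
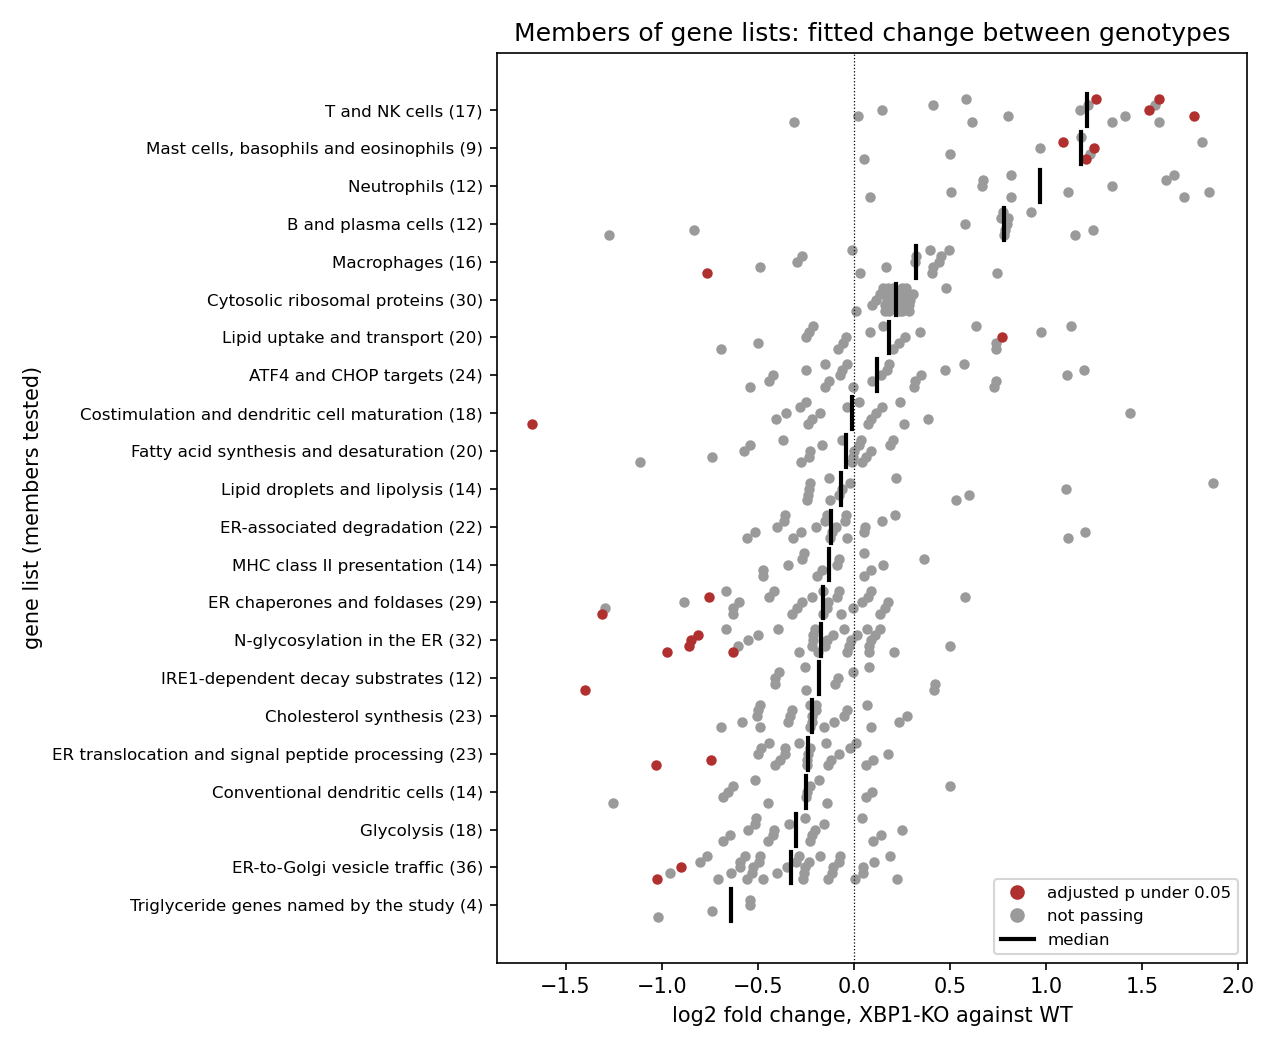
Log2 fold change of XBP1-KO against WT for each tested member of 22 gene lists, with the median of each list as a bar and members with an adjusted p under 0.05 in red. Medians run from -0.64 for the 4 triglyceride genes and -0.33 for ER-to-Golgi traffic to 1.21 for T and NK cell genes.

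Other outputs of the ER stress response, mRNA decay by IRE1 and the PERK arm, were read from lists of their own. Of 12 genes known from other studies as substrates of IRE1-dependent mRNA decay, 9 lay lower, 1, Itgb2, fell and 2 fell when adjusted over the list alone. The list had a camera adjusted p of 0.047 and an adjusted p = 0.37 with an estimated correlation. This call ended without WT a (0.1), WT c (0.11), XBP1-KO b (0.13) and XBP1-KO c (0.058), with libraries WT b and XBP1-KO b as a batch term (0.066) and in the other 4 libraries alone (0.072). Without Itgb2 the list had an unadjusted p of 0.11. Itgb2 itself kept an adjusted p between 0.000866 and 0.0387 whichever library was left out. Of 24 targets of ATF4 and CHOP, transcription factors of the PERK arm, 13 lay higher, 11 lower and none passed (adjusted p = 0.39). The smallest p among them was that of Cebpb, with 19.9 ± 2.54 CPM in WT and 29.6 ± 4.15 CPM in XBP1-KO and an adjusted p of 0.165.

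Itgb2 pairs with the alpha chains CD11a to CD11d, and the genes of 3 of them, which lie side by side on chromosome 7, were looked at after the value of Itgb2 was seen. Itgam, the chain CD11b, fell from 496 ± 80.9 to 265 ± 44.9 CPM with an adjusted p of 0.0306. With 1 library left out Itgam passed only without XBP1-KO b (0.00906) and not without WT a (0.0569), WT b (0.0708), WT c (0.116), XBP1-KO a (0.149) or XBP1-KO c (0.125). Itgad, the chain CD11d, rose from 0.517 ± 0.164 to 5.3 ± 1.19 CPM, a log2 fold change of 3.35 (SE 0.38) with an adjusted p of 0.00279. Itgax, the chain CD11c, had 103 ± 7.95 CPM in WT and 146 ± 14.2 CPM in XBP1-KO with an adjusted p of 0.106. Cox6a2, a muscle-type subunit of cytochrome c oxidase whose gene follows Itgad, had 3.06 ± 1.8 CPM in WT and 16.7 ± 8.7 CPM in XBP1-KO, a log2 fold change of 2.45 (SE 0.49) with an adjusted p of 0.0877, which passed without WT a at 0.0472 and not without any other library.

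**Figure D3:**
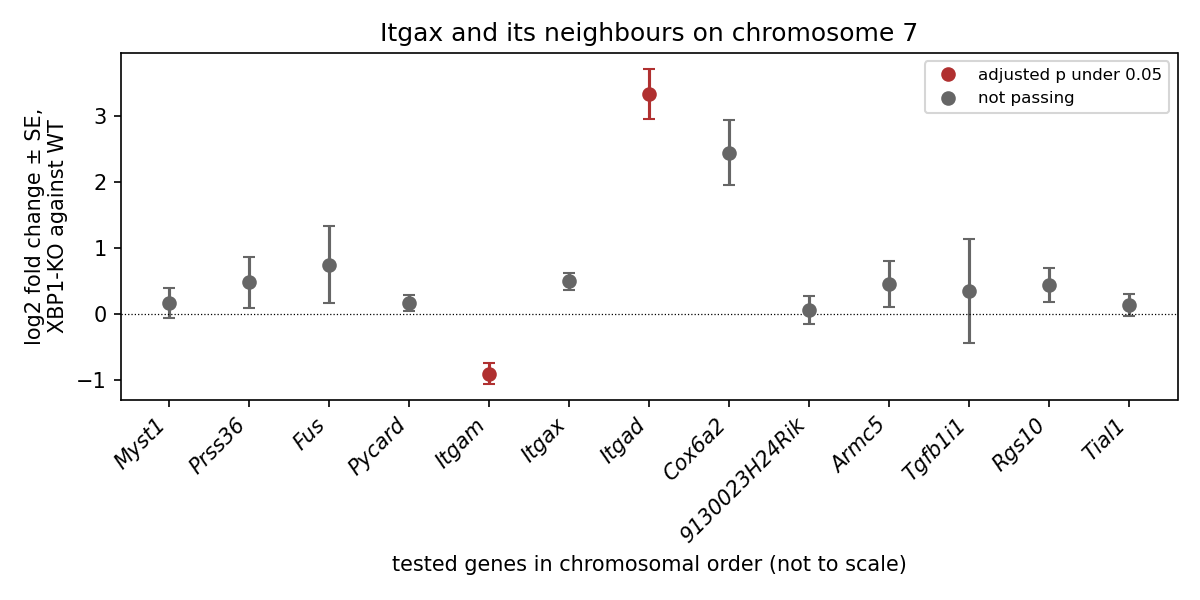
Log2 fold change of XBP1-KO against WT, with its standard error, for 13 tested genes around Itgax in their order on chromosome 7, not drawn to scale, with adjusted p under 0.05 in red. Itgad at 3.35 and Cox6a2 at 2.45 stand above the other genes, and Itgam lies at -0.90.

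Lipid metabolism was examined because the study names triglyceride synthesis. The 4 genes that the study names were chosen on these samples, so neither their direction nor any test of this list is independent evidence. Fasn, the fatty acid synthase, had 35.3 ± 6.8 CPM in WT and 21.2 ± 0.996 CPM in XBP1-KO, Lpar1 79.4 ± 27.4 and 39.1 ± 8.02 CPM, Agpat6 92.7 ± 13.3 and 63.8 ± 13.6 CPM, and Scd2, a stearoyl-CoA desaturase, 109 ± 15.1 and 74.9 ± 17.8 CPM. Their adjusted p-values over all genes were 0.0815, 0.138, 0.177 and 0.203, so none passed, and adjusted over the list alone all 4 did. Lpar1 passed without WT b (0.0407) and Agpat6 without XBP1-KO b (0.0459). Over the tests of the 22 alternatives the adjusted p ran from 0.00853 to 0.738 for Fasn and 0.00314 to 0.918 for Lpar1. It ran from 0.0324 to 0.477 for Agpat6 and 0.0875 to 0.799 for Scd2. The list had a camera adjusted p of 0.00075, and an adjusted p = 0.26 with an estimated correlation. Of 20 genes of fatty acid synthesis, 13 lay lower, none passed and 4 fell when adjusted over the list alone, with a camera adjusted p of 0.031 and an adjusted p = 0.37 with an estimated correlation. This call ended without WT a (0.077), without XBP1-KO b (0.12), with a filter at a CPM of 1 (0.068), with the authors' gene filter (0.061), with the deposited CPM (0.061 and 0.068), with the trends over GC content and length removed (0.051) and in the 4 libraries other than WT b and XBP1-KO b (0.098). Its median of -0.04 lay above 0 with upper quartile scaling and with library size alone. Of 23 genes of cholesterol synthesis, 19 lay lower, none passed and 4 fell when adjusted over the list alone. The list had an adjusted p of 0.00073, and an adjusted p = 0.67 with an estimated correlation; without XBP1-KO b it was 0.074. Its mean log2 CPM lay below every WT library in 2 XBP1-KO libraries, while XBP1-KO a at 5.46 lay above WT b at 5.22.

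Of 21 genes of glycerolipid synthesis, 11 lay lower and Agpat4, an acyltransferase, fell from 38.2 ± 3.9 to 20.2 ± 0.42 CPM with an adjusted p of 0.0242, while the list did not pass (0.31) and 4 of its genes fell when adjusted over the list alone. Apoe, the lipid carrier apolipoprotein E, rose from 234 ± 24.9 to 398 ± 18.5 CPM with an adjusted p of 0.0242. It was the only call among 20 genes of lipid uptake and transport, of which 12 lay higher and 4 rose and 2 fell when adjusted over the list alone (list adjusted p = 0.34). Agpat4 passed without XBP1-KO b (0.0357) and not without WT a (0.0513), WT b (0.0662), WT c (0.116), XBP1-KO a (0.0734) or XBP1-KO c (0.0927). Apoe passed without WT a (0.0395) and XBP1-KO b (0.0357) and not without WT b (0.0662), WT c (0.197), XBP1-KO a (0.069) or XBP1-KO c (0.118). Of 14 genes of lipid droplets and lipolysis, 9 lay lower and none passed (list adjusted p = 0.97), with a median of -0.07 that lay above 0 with library size alone, a mean of 0.21 and a test direction that was lower. Adjusted over the list alone 1 gene rose. The mean log2 CPM of this list was 4.52 to 4.66 in the XBP1-KO libraries, above the 4.4 to 4.44 of the WT libraries. G0s2, an inhibitor of lipolysis, had 0.698 ± 0.395 CPM in WT and 2.56 ± 0.896 CPM in XBP1-KO and an adjusted p of 0.121.

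Among genes of antigen presentation and activation, few passed, and adjusted over the list alone at most 1 gene changed in each list of this paragraph. Il12b was the only call among 18 genes of costimulation and maturation, of which 9 lay higher and 9 lower (list adjusted p = 0.16, and 0.031, lower, without XBP1-KO a; its median of -0.006 lay above 0 with upper quartile scaling and library size alone), and among 21 inflammatory cytokines and chemokines, of which 14 lay higher (0.31). It passed without WT a (0.0305) and XBP1-KO b (0.0389) and not without WT b (0.101), WT c (0.18), XBP1-KO a (0.0631) or XBP1-KO c (0.0927). Mrc1, the mannose receptor CD206, fell from 560 ± 30.8 to 330 ± 58.9 CPM with an adjusted p of 0.0455. With 1 library left out Mrc1 passed only without XBP1-KO b, at 0.0108, and lay at 0.0726, 0.0694 and 0.243 without WT a, b and c and at 0.179 and 0.166 without XBP1-KO a and c. It was the only call among 18 immunosuppressive mediators, of which 10 lay higher, with a median of 0.06, a test direction that was lower and a list adjusted p of 0.9. Ciita, the transactivator of MHC class II genes, had 189 ± 26 CPM in WT and 136 ± 6.33 CPM in XBP1-KO (adjusted p = 0.131), and of 14 genes of MHC class II presentation 9 lay lower (list adjusted p = 0.19). This list passed, lower in XBP1-KO, without WT b (0.022) and with the trends over GC content and length removed (0.025). Tapbp, the peptide-loading protein tapasin, had 289 ± 7.81 CPM in WT and 217 ± 25.7 CPM in XBP1-KO (adjusted p = 0.174), and of 18 genes of MHC class I presentation 9 lay higher and 9 lower (list adjusted p = 0.39).

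Of 18 glycolysis genes 14 lay lower, none passed and 4 fell when adjusted over the list alone. Hk1, a hexokinase, had 42.8 ± 5.43 CPM in WT and 26.7 ± 3.89 CPM in XBP1-KO (adjusted p = 0.089, and 0.046 without XBP1-KO b). The list had an adjusted p of 0.00026, and an adjusted p = 0.53 with an estimated correlation. Its mean log2 CPM was highest within each genotype in the b libraries, at 6.55 in WT b and 6.27 in XBP1-KO b. XBP1-KO b lay above WT a (6.19) and WT c (6.22), so that the genotypes overlapped. Interferon-stimulated genes had 17 of 26 lower (list adjusted p = 0.067), with Ifih1 at 39.9 ± 5.53 CPM in WT and 29.1 ± 1.29 CPM in XBP1-KO (adjusted p = 0.214). This list passed, lower in XBP1-KO, without WT a (0.0082), XBP1-KO a (0.034) or XBP1-KO b (0.039), without a filter on low counts (0.032) and with libraries WT b and XBP1-KO b as a batch term (0.041). Of 19 genes of the oxidative stress response 14 lay higher (list adjusted p = 0.23), with Txn1 at 150 ± 10.5 CPM in WT and 187 ± 11.4 CPM in XBP1-KO (adjusted p = 0.29). Of 24 genes of cell division 15 lay lower and 3 fell when adjusted over the list alone, with a median of -0.02 that lay above 0 with upper quartile scaling and library size alone (list adjusted p = 0.16, and 0.0032 without WT c), with the mitotic kinase Bub1b at 43.1 ± 9.02 CPM in WT and 24.1 ± 2.54 CPM in XBP1-KO (adjusted p = 0.0565, and 0.0389 without XBP1-KO b). Over the tests of the 22 alternatives the adjusted p ran from 0.00138 to 0.265 for Bub1b and 0.0125 to 0.371 for Hk1.

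Markers of dendritic cells and macrophages were abundant in both genotypes. Cd209a had 1632 ± 343 CPM in WT and 1378 ± 314 CPM in XBP1-KO and Clec10a 261 ± 20.2 and 220 ± 6.11 CPM, with adjusted p-values of 0.634 and 0.414. Of 14 markers of conventional dendritic cells 11 lay lower and none passed, while 1 rose and 2 fell when adjusted over the list alone, with a list adjusted p of 0.031, and an adjusted p = 0.37 with an estimated correlation. This call ended without WT b (0.078), XBP1-KO a (0.14) and XBP1-KO b (0.05). C1qb, a complement component of macrophages, had 2912 ± 579 and 3270 ± 376 CPM and Cd68 1029 ± 127 and 1050 ± 79.9 CPM, with adjusted p-values of 0.707 and 0.944. Of 16 macrophage markers 11 lay higher and Mrc1 was the only call (list adjusted p = 0.61). Ccr2, the receptor that draws monocytes into tissue, had 2695 ± 412 CPM in WT and 1722 ± 130 CPM in XBP1-KO (adjusted p = 0.0785), and F13a1 831 ± 117 and 605 ± 369 CPM (adjusted p = 0.701). F13a1 had 1031 CPM in XBP1-KO b, 403 and 381 CPM in XBP1-KO a and c and between 715 and 950 CPM in WT. Without XBP1-KO b its log2 fold change went from -0.46 to -1.09 with an adjusted p of 0.0068, and in the 4 libraries other than WT b and XBP1-KO b it was -0.99 with 0.0195. Ccr2 passed without WT b (0.0466), and over the tests of the 22 alternatives its adjusted p ran from 0.00568 to 0.536. Of 10 monocyte markers 5 lay higher and 5 lower (list adjusted p = 0.67). Of 10 markers of plasmacytoid dendritic cells 6 lay lower (list adjusted p = 0.9), with a median of -0.005 that lay above 0 with upper quartile scaling (0.049) and library size alone (0.064), and a mean of 0.21. Tcf4 had 83.6 ± 1.28 and 85.6 ± 12.8 CPM and Ly6d 32.7 ± 18.1 and 59.7 ± 15.7 CPM, with adjusted p-values of 0.938 and 0.513.

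The lists of T and NK cells and of mast cells, basophils and eosinophils had a mean log2 CPM in every XBP1-KO library above that of every WT library. Of 17 T and NK cell genes 16 lay higher, 4 rose and 11 rose when adjusted over the list alone, with a camera adjusted p of 3.2e-07 and an adjusted p = 0.37 with an estimated correlation. The most abundant members were Klrk1, with 89.7 ± 13.9 CPM in WT and 91.1 ± 10.9 CPM in XBP1-KO, and Klrb1c, with 54 ± 8.16 and 59.6 ± 9.41 CPM, and neither passed (adjusted p = 0.963 and 0.736). Of 9 genes of mast cells, basophils and eosinophils all lay higher, 3 rose and 6 rose when adjusted over the list alone. The 3 were the mast cell proteases Cma1, from 14.5 ± 1.05 to 34.4 ± 8.29 CPM, Tpsb2, from 13.4 ± 1.92 to 28.5 ± 7.65 CPM, and Cpa3, from 9.68 ± 0.39 to 22.3 ± 7.21 CPM. The list had a camera adjusted p of 0.00013, and an adjusted p = 0.37 with an estimated correlation. The 4 T and NK calls numbered 0 without WT a, WT c or XBP1-KO a, 2 without WT b and 3 without XBP1-KO b, and the 3 mast cell calls 1 without WT a and 0 without WT b, WT c, XBP1-KO a or XBP1-KO c.

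Of 12 B and plasma cell genes 10 lay higher and none passed, while 6 rose and 1 fell when adjusted over the list alone, with a list adjusted p of 0.00075, and an adjusted p = 0.5 with an estimated correlation. Cd79b had 72.9 ± 28.3 CPM in WT and 127 ± 23.7 CPM in XBP1-KO (adjusted p = 0.264) and Ms4a1 67.6 ± 32.4 and 115 ± 17.7 CPM (0.422). All 12 neutrophil genes lay higher and none passed, with a list adjusted p of 0.019, and an adjusted p = 0.52 with an estimated correlation. This call ended without WT b (0.083), without XBP1-KO c (0.087) and with library size alone (0.054). The mean log2 CPM of the neutrophil list was 4.48, 1.83 and 2.59 in WT and 4.78, 2.4 and 5.05 in XBP1-KO a, b and c, so that XBP1-KO b lay below WT a and WT c. That of the B cell list overlapped too, with XBP1-KO b at 3.68 below WT a at 3.78. Retnlg had 41.9 ± 25.6 and 129 ± 7.29 CPM (adjusted p = 0.304) and S100a8 24.7 ± 22.3 and 88.8 ± 24.7 CPM (0.433). Retnlg passed without WT b (0.048) and S100a8 without WT a (0.0224). Over the tests of the 22 alternatives the adjusted p ran from 0.0033 to 0.736 for Retnlg and 0.0211 to 0.749 for S100a8. The lists of tumour epithelium and mesothelium (12 genes, 8 higher, adjusted p = 0.65), fibroblasts (6 genes, 4 higher, 0.9), endothelium (6 genes, 4 lower, 0.65) and red cells and platelets (7 genes, 5 higher, 0.46) did not pass. Over the tests of the 22 alternatives the adjusted p ran from 0.0035 to 0.94 for the epithelium list and 0.02 to 0.89 for red cells and platelets. In these 4 lists, Krt19 had 60.4 ± 11.1 and 54.2 ± 14.1 CPM, Krt18 27.4 ± 5.41 and 30.9 ± 9.1 CPM, Dcn 39.1 ± 2.89 and 45.1 ± 12.2 CPM and Fap 2.85 ± 0.881 and 4.02 ± 2.27 CPM in WT and XBP1-KO. Pecam1 had 10.2 ± 3.2 and 9.97 ± 3.35 CPM, Vwf 8.49 ± 2.85 and 7.47 ± 1.5 CPM, Pf4 131 ± 37.1 and 266 ± 141 CPM and Beta-s 55.2 ± 67.3 and 59.4 ± 68 CPM in WT and XBP1-KO.

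**Figure D4:**
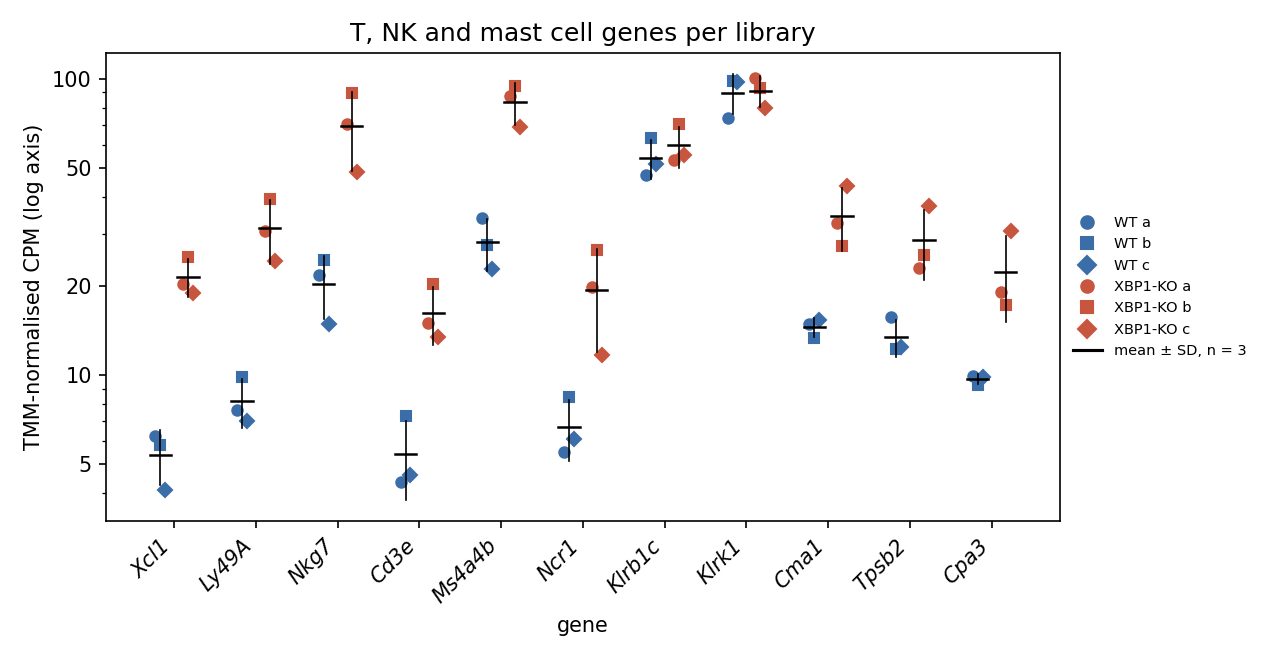
Normalised level (TMM-normalised CPM, log axis) of 8 genes known from T and NK cells and 3 from mast cells in each library, with the mean and SD of the 3 libraries of each genotype. Every XBP1-KO library lies above every WT library for the genes other than Klrb1c and Klrk1, as for Nkg7 with means of 20.4 and 69.4 CPM.

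Genes that mark RNA quality or handling were examined as lists too. Of 30 cytosolic ribosomal protein genes all lay higher and none passed, with a median of 0.22, a list adjusted p of 0.00026, and an adjusted p = 0.72 with an estimated correlation. This call ended without WT b (0.38), in the 4 libraries other than WT b and XBP1-KO b (0.055), and with the trends over GC content and length removed (0.31). Rps19 had 1520 ± 258 CPM in WT and 1827 ± 132 CPM in XBP1-KO and Rpl4 1491 ± 171 and 1616 ± 101 CPM. Of 28 genes of mitochondrial oxidative phosphorylation 24 lay higher and none passed (list adjusted p = 0.16, and past the threshold with library size alone at 0.029, limma-voom at 0.045 and the deposited CPM at 0.019 and 0.021), with Atp5a1 at 672 ± 28.8 and 628 ± 16.9 CPM and Cox4i1 at 509 ± 78.3 and 585 ± 49.8 CPM. Of 20 immediate early and heat shock genes 10 lay higher and 10 lower (list adjusted p = 0.97), with Hspa8 at 6463 ± 888 and 5161 ± 1276 CPM and Zfp36 at 527 ± 60.1 and 479 ± 54.8 CPM. The 3 sex-linked genes did not pass (list adjusted p = 0.97), with a median of 0.27 and a test direction that was lower. Xist had 270 ± 8.27 and 224 ± 26.4 CPM and Kdm5d 8.76 ± 2.75 and 10.6 ± 3.31 CPM, so that both were read in all 6 libraries. Of the 38 lists 16 passed with the preset correlation, 11 lower and 5 higher in XBP1-KO, 0 with an estimated correlation, where the smallest adjusted p was 0.26, and 4 with fry. The triglyceride list, chosen on these samples, is among the 11 and among the 4.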

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

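The authors' gene filter, the removal of trends over GC content and length, the T and NK score as a covariate, the batch term, the 4 libraries alone and the list without Itgb2 were chosen after seeing the data; the other alternatives were chosen before the data were examined. No paired analysis was possible because the columns carry the genotype and no replicate number. Among 75 named genes, 42 of 1650 values under the alternatives turned direction, in 20 genes, and neither value of these pairs was called. Against 71 changed genes (25 higher, 46 lower), DESeq2-style size factors in edgeR gave 71, of which 68 were shared. Upper quartile factors gave 27 lower genes of 50, library size only 25 genes (13 higher, 12 lower), no low-count filter 252 (61 higher, 191 lower), no robust estimation 45 (27 lower), the likelihood ratio test 308 (109 higher, 199 lower), DESeq2 484 (108 higher, 376 lower) and limma-voom 47 (30 lower). The authors' CPM gave 25 genes (13 higher, 12 lower) with pseudocount 1 and 13 (12 higher, 1 lower) with pseudocount 0.1. An adjusted p under 0.01 gave 6 (5 higher, 1 lower), under 0.1 252 (59 higher, 193 lower), and a change of at least 2-fold 36 (13 lower). With GC and length trends removed 21 genes passed (11 higher, 10 lower), with the batch term 426 (93 higher, 333 lower), and in the other 4 libraries 13 genes were higher. With the T and NK score as covariate edgeR called 0 genes (0 higher, 0 lower) and 1592 had an unadjusted p under 0.05; genotype takes 81.7% of that score's variance, so this fit can hardly part the score from genotype. Elsewhere the cause was not tested.

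Leaving out 1 library at a time gave from 5 to 154 changed genes, 4 to 32 higher and 1 to 122 lower, and a log2 fold change of Xbp1 between -1.083 and -0.747. Xbp1 passed at -0.905 without a filter, -0.874 with a CPM of at least 1 and with the batch term, -0.892 with the likelihood ratio test, -0.914 with DESeq2, -0.879 with the authors' gene filter and -0.999 in the other 4 libraries. With the T and NK score as covariate its log2 fold change was -0.233 with an adjusted p of 0.882. The lists' adjusted p without 1 library ran from 7.9e-05 to 0.0011 for chaperones, 2.5e-05 to 0.003 for translocation, 0.0039 to 0.28 for ER-associated degradation, 2e-05 to 0.005 for N-glycosylation, 1.5e-08 to 1.1e-07 for ER-to-Golgi traffic, 0.027 to 0.13 for IRE1-dependent decay, 0.00069 to 0.0034 for triglyceride genes and 1e-08 to 2.2e-05 for T and NK cells. The triglyceride genes were chosen on these samples, so the values of their list are not independent evidence.

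With an estimated correlation the adjusted p was 0.26 for chaperones, ER-to-Golgi traffic and triglyceride genes, 0.37 for translocation, N-glycosylation, IRE1-dependent decay and T and NK cells, and 0.52 for ER-associated degradation. With fry it was 0.025 for chaperones and ER-to-Golgi traffic, 0.036 for triglyceride genes and 0.032 for fatty acid synthesis, the 4 lists that passed. It was 0.073 for translocation, N-glycosylation and T and NK cells, 0.33 for ER-associated degradation and 0.19 for IRE1-dependent decay. With the T and NK score as covariate it was 0.063 for chaperones, 0.39 for translocation and triglyceride genes, 0.4 for N-glycosylation and 0.87 for IRE1-dependent decay, and the direction turned for ER-associated degradation (0.34), T and NK cells (0.93), cholesterol synthesis (0.44), macrophages (0.042) and red cells and platelets (0.02). IRE1-dependent decay had 0.066 with the batch term, 0.072 in the other 4 libraries and, without Itgb2, an unadjusted p of 0.11; ER-associated degradation had 0.15 in the other 4 libraries. Over 22 alternatives the chaperone, translocation, degradation, N-glycosylation and ER-to-Golgi lists passed in 20, 19, 16, 19 and 21. The likelihood ratio test and the fit without robust estimation give no list values, since camera does not use them. Depth limits genes of a few counts; for most genes the spread between libraries, with a biological coefficient of variation of 0.25, limits the precision.

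Directions that turned are given as log2 fold changes for genes and adjusted p for lists. Of 837 list values 60 turned, in 18 lists, and in 5 of them, all with the T and NK score as covariate, the list was called before or after. With that covariate Cd209a had 0.63, Scd2 0.292, Krt19 0.89, Zfp36 0.086, Cebpb -0.001, Cd68 -0.144, Klrk1 -0.164, Klrb1c -0.386, Fap -0.452, Pf4 -0.618, Kdm5d -1.141 and Beta-s -4.456, and the lists of MHC class II had 0.4, lipid uptake 0.3, cytokines 0.38, oxidative stress 0.87, monocytes 0.28 and plasmacytoid dendritic cells 0.44. With GC and length trends removed Cd68 had -0.082, Vwf 0.012, Pecam1 0.066, Beta-s -0.173 and Cox4i1 -0.024, oxidative phosphorylation 0.65, and lipid droplets, immediate early and sex-linked genes 0.84. Pecam1 had 0.026 with upper quartile factors, 0.04 with library size only, and 0.037 and 0.04 with the authors' CPM (pseudocount 1 and 0.1). In the other 4 libraries Cd68 had -0.146, C1qb 0 after rounding, macrophages 0.66 and sex-linked genes 0.93. Lipid droplets had 0.99 with upper quartile factors, 0.93 without a low-count filter, with DESeq2 and with the authors' gene filter, 0.89 and 0.91 with the authors' CPM and 0.77 with fry. Immunosuppressive mediators had 0.89 and 0.86 with the authors' CPM, 0.8 with the authors' gene filter and 0.96 with fry. Plasmacytoid dendritic cells had 0.67 with DESeq2, 0.93 with limma-voom and 0.96 with fry. Immediate early genes had 1 with library size only, 0.92 without a low-count filter and 0.96 with the batch term. Sex-linked genes had 0.99 with a CPM of at least 1, 0.98 with the authors' gene filter, 0.96 with fry and 0.82 with the batch term.

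With 1 library left out the log2 fold change ran from -0.121 to 0.098 for Tcf4, -0.016 to 0.268 for C1qb, -0.094 to 0.097 for Cd68, -0.104 to 0.088 for Klrk1, -0.006 to 0.242 for Klrb1c, -0.117 to 0.347 for Krt18, -0.059 to 0.339 for Dcn, -0.047 to 0.784 for Fap, -0.32 to 0.233 for Pecam1, -0.427 to 0.022 for Vwf, -1.451 to 1.822 for Beta-s and -0.002 to 0.17 for Rpl4. The adjusted p of lists that turned ran from 0.56 to 0.96 for lipid droplets, 0.52 to 0.94 for immunosuppressive mediators, 0.41 to 0.89 for plasmacytoid dendritic cells, 0.28 to 0.92 for macrophages, 0.35 to 0.84 for monocytes, 0.27 to 0.94 for tumour epithelium, 0.26 to 0.91 for endothelium, 0.11 to 0.84 for red cells and platelets, 0.48 to 0.86 for immediate early genes and 0.56 to 0.98 for sex-linked genes.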

Other observations

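The tests on the share of the main cell type, on integrin paralogs and on extra gene copies were chosen only after the results were seen, as were the genes of the next paragraph.

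Libraries WT b and XBP1-KO b shared several levels apart from the other 4. Hba-a2, a haemoglobin chain, had 82.5 and 92.6 CPM in them and between 8.75 and 12.2 CPM in the others. Ccl7, a chemokine that attracts monocytes, had 171.9 and 354.4 CPM in them and between 43.8 and 96.2 CPM in the others, and Thbs1, a matrix glycoprotein, 144.8 and 128.3 CPM against 27.1 to 58.9 CPM. Retnla, a gene of alternatively activated macrophages, had 1143 and 855.4 CPM in them and between 1782 and 7321 CPM in the others. The deviations of these libraries from their genotype's mean correlated at 0.274 across all 15958 tested genes, which are not independent replicates. Those of the other 8 pairings of a WT with an XBP1-KO library correlated between -0.197 and 0.113. In 561 genes both libraries lay beyond the others of their genotype, in the same direction and by a set margin. In the other pairings this held for 178 to 338 genes.

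The called mast cell proteases were picked for their rise, and their difference from other mast cell genes was not tested. On a second list of 12 mast cell genes 7 lay higher, with a median log2 fold change relative to all genes of 0.165 (bootstrap bounds -0.363 and 0.365). Its most abundant members were Il1rl1, the IL-33 receptor, with 58.4 CPM in WT and 37.4 CPM in XBP1-KO, and Slc18a2, a monoamine transporter, with 41.4 and 39.4 CPM. Neither passed, with adjusted p-values of 0.106 and 0.883 in edgeR's quasi-likelihood test.

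The count of 71 changed genes was compared with that of the other ways to split the 6 libraries into groups of 3. Of the 10 splits 1, the real one, gave as many, and the highest of the other 9 gave 0, with between 164 and 1148 genes at an unadjusted p under 0.05 in edgeR. With 10 splits the share cannot fall under 0.05. Each of the other 9 also mixes the genotypes within its groups, so any genotype difference widens their spread and keeps their counts low.

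Lower levels of secretory-pathway genes in XBP1-KO are set against 2 technical explanations. After each library's trend over GC content and transcript length was removed, the median of the 142 genes relative to all genes was -0.269 (bounds over genes, not libraries, -0.328 and -0.215) against -0.273 before, which argues against that trend as the whole cause, although 21 genes in place of 71 then passed. Dilution by RNA of other cells stays open, since a second list of 18 abundant myeloid genes, 3 of them in another list, had a median of -0.17 (bounds -0.264 and -0.079), between no change and the secretory median. The most abundant of these, Lyz2 and Ctsb, had 15670 and 6760 CPM in WT and 13880 and 6654 CPM in XBP1-KO. Loss of XBP1 in the dendritic cells, which the design names, stays open too, and no test here separates it from dilution.

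Higher T and NK cell transcripts in XBP1-KO may come from T and NK cells among the sorted cells, as a second list of 25 such genes had a median of 0.874 relative to all genes (bounds 0.506 and 1.081), with 23 higher. In WT 11 of the 17 genes of the first list and 9 of the 25 of the second reached 5 CPM, and neither shares a gene with another list; the most abundant members were Klrk1 (89.7 and 91.1 CPM in WT and XBP1-KO) and Klrb1c (54 and 59.6 CPM) of the first and Il7r (44.9 and 42.1 CPM) and Il2ra (29.7 and 23.7 CPM) of the second, and they did not share the rise. All 3 XBP1-KO libraries had a score above every WT library, which argues against a single knockout library as the cause. The T and NK list lay 1.163 above the epithelium, fibroblast and endothelium lists pooled (bounds 0.447 and 1.465, over genes and not libraries). In mean log2 CPM over libraries, XBP1-KO lay 0.95 above WT for the T and NK list. For epithelium, fibroblasts and endothelium the differences were 0.25, 0.05 and -0.13. These values argue against an equal rise of all other cell types, although the fibroblast and endothelium lists lay low, at 1.45 and 1.25 in WT. Left out of this comparison were mast cells, neutrophils and B cells, with median log2 fold changes of 1.18, 0.97 and 0.78. The T and NK list had 1.21 and red cells and platelets 0.11. A lower share of the main cell type beside these immune cells therefore stays open. Whether such cells passed the sort, whose gate is not given in the sources used here, or lay in the tumours in other numbers in XBP1-KO stays open, as does expression of these genes by the dendritic cells themselves.

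Itgax, Itgad and Cox6a2, adjacent genes, lay higher in XBP1-KO with a mean log2 fold change of 2.097, and these mice delete XBP1 through CD11c, which Itgax encodes. Reads shared between integrin paralogs do not account for Cox6a2, which is no integrin and lay higher by 2.449 (SE 0.49). A candidate explanation is extra gene copies carried with the Cre transgene, where that was made from a long stretch of DNA around Itgax; the sources used here do not give the strain. Of 13730 runs of 3 neighbouring genes, 4 had a mean as high (0.029%), this run included. The other 3 overlap and all hold Xlr3c, at 0 CPM in every WT library, so their means are no measured folds. The mean of the Itgax run rests on low WT levels too, 0.517 CPM for Itgad and 3.06 ± 1.8 CPM for Cox6a2. In edgeR's quasi-likelihood test Itgax, at 0.497, and Cox6a2 did not pass (adjusted p = 0.106 and 0.0877). The run was picked for its height, though, and Itgam on the other side was lower. Extra copies cannot be told apart from regulation of these genes or from a change in the mix of sorted cells.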
